A study of Mus musculus with 12 samples.

How the data were processed

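Expression was measured with Affymetrix mouse gene arrays in regulatory T cells (Treg) sorted by flow cytometry from the spleens of DEREG mice. In these mice cells that express Foxp3, the lineage-defining transcription factor of Treg, carry the diphtheria toxin receptor fused to a green fluorescent protein, so that diphtheria toxin (DTx) depletes them. Per the labels' protocols, 2 ng of RNA per sample went through a whole-transcript amplification for small amounts of RNA. The deposited values were log2 expression values per probe set, and per the submitters' processing notes the authors made them with oligo and RMA, which corrects background, normalizes between arrays and summarises the probes of a probe set. Versions and settings of these tools were not given in the sources used here.

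The table held 41345 rows in 12 arrays. The probe annotation used here gave exactly 1 gene symbol for 23521 rows (22180 genes), several for 1814 and none for 16010. Of the 23521 rows, 23328 had a gene number found in the RefSeq gene table of the GRCm38.p6 assembly, which was used for names only, and the others kept the annotation's name. Rows with 1 symbol were tested, each probe set on its own, and where 1 value per gene was needed the probe set with the highest mean over all 12 arrays was taken. Of 1082 genes with several probe sets, 2 in iTreg minus eTreg and 3 in iTreg minus e_iTreg had probe sets past the threshold in opposite directions. No genome build was named for the arrays, so positions are not given.

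Arrays were grouped as the series design gives them, 4 biological replicates per group, and 1 linear model was fitted to all 3 groups with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 9 residual degrees of freedom, prior degrees of freedom 5.78). Each contrast was tested two-sided and adjusted by the Benjamini-Hochberg method over the 23521 rows, with a threshold of adjusted p 0.05 and no fold threshold. The p-values measure the spread between these samples, and the number of arrays limits the precision. The median SE of a log2 difference was 0.121. In 10 simulated sets of 23521 rows with 200 changed genes each, the same fit found 97.0%, 97.6% and 97.2% of genes changed by a log2 value of 1 in e_iTreg minus eTreg, iTreg minus eTreg and iTreg minus e_iTreg. It found 41.6%, 41.5% and 40% of those changed by 0.5, and the noise in those sets was independent between genes.

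Before the data were examined, 30 gene lists were fixed, among them markers of other cell types that a splenic sort could hold. They were tested with camera at the preset inter-gene correlation of 0.01, on 1 probe set per gene, with Benjamini-Hochberg adjustment over the 30 lists of a contrast. Camera with the correlation estimated from the data and fry were run beside it. At the preset correlation 4, 20 and 18 lists passed in e_iTreg minus eTreg, iTreg minus eTreg and iTreg minus e_iTreg, and with the estimated correlation none of the 30 lists passed in any of the 3 contrasts, with smallest adjusted p-values of 0.960, 0.0974 and 0.162. Fry, which tests whether the genes of a list move on balance 1 way without comparing them with other genes, passed 0, 16 and 10 lists. The signs of median, mean and test differed for 9, 1 and 1 lists, and of those lists 0 were past the threshold in each contrast.

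Genes were named by a rule fixed before the data were examined. It took the 12 largest rises and 12 largest falls among genes past the threshold and, where fewer than 10 passed, the 8 smallest p-values in each direction. It also took up to 4 members of each list with the smallest p, and always Foxp3, Il2ra, Ctla4, Ikzf2 and Nrp1. Predicted gene models, small RNAs, receptor segments and rows with several genes were left out of the first 2 parts but counted, and not every gene so chosen was printed. Members outside the rule that complete a count of 5 or fewer, and Cd8b1, Ccl5 and Prf1, were chosen after their values were seen, and they are Fas, Nt5e, Izumo1r, Pdk1, Dnajb9, Lrrc32 against e_iTreg, Fasl, Tnfrsf10b, Slamf6, Tox and Atf4.

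Alternatives fixed beforehand were quantile normalization or median centring of the deposited values, filters on dim probe sets (above the median, or above log2 6), all rows tested, 1 probe set per gene, other error models, array weights, a fit of the compared groups alone, the replicate number as a block, adjusted p 0.1, a fold of at least 1.5 and leaving out each array in turn. Chosen after seeing the data were fits without 3 arrays with the signal of 1 sex, without 3 arrays with low B cell markers, and with marker means or sex-linked genes as covariates, and the position of e_iTreg with the eTreg arrays split. Correlations between contrasts that share a group were set beside simulated groups with no effect, and 35 splits of the 8 arrays of each contrast were refitted. Rows with several or no symbol were fitted together with the others only in the alternative on all rows.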

Results

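The series asked how Treg induced by intravenous immunoglobulin (IVIg), pooled IgG given at 2 g/kg, differ from endogenous Treg in mice with ovalbumin-induced allergic airways disease. Splenic Treg of 3 groups were profiled on 4 arrays each. The eTreg group came from mice given human serum albumin (HSA), the control protein, at 2 g/kg and, per the series design, no DTx. The e_iTreg group came from mice given IVIg with no DTx, and the labels call it a mixture of endogenous and induced Treg. The iTreg group came from mice whose endogenous Treg were depleted with DTx at 40 ng/g and which were given IVIg. The growth protocol, worded alike for all samples, places DTx before IVIg or HSA, and the grouping here follows the series design. If HSA mice had DTx too, the contrasts with eTreg would have another meaning. No group with DTx and HSA was analysed here, so under that design IVIg and DTx changed together between iTreg and eTreg. Changes below are log2 differences ± SE with n = 4 arrays per group, and levels are mean log2 values ± SD.

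The iTreg arrays stood apart from the other 8. The first principal component held 40.2% of the variance, and on it iTreg arrays lay between -35.5 and -22.9, eTreg arrays between -2.13 and 24.3 and e_iTreg arrays between -1.51 and 28.6. Pairwise correlations ranged from 0.966 to 0.993. Foxp3 was at 12.46 ± 0.09 in eTreg, 12.30 ± 0.21 in e_iTreg and 12.17 ± 0.25 in iTreg (n = 4 each) and was not past the threshold in any contrast.

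The first comparison, e_iTreg minus eTreg, asked what IVIg changed while endogenous Treg were present. No gene passed limma's test, against 1649 rows (7.01%) with an unadjusted p under 0.05, and the smallest adjusted p over all rows was 0.223. Among named genes the smallest p-values went to Zfp820, a zinc finger gene, with a difference of 0.56 ± 0.12, and to Fat2, an atypical cadherin, with 0.37 ± 0.09. In the other direction were Ifi213, of the interferon-inducible Ifi200 family, at -0.75 ± 0.17, the mitochondrial ND4L at -0.74 ± 0.17, Rsl1 at -0.87 ± 0.22 and the complement regulator Cd46 at -0.63 ± 0.16. Each of these 6 had adjusted p = 0.704. Zfp820 and Fat2 were dim, at 4.13 and 5.28 in eTreg and 4.69 and 5.65 in e_iTreg, below the log2 6 filter. Foxp3 differed by -0.16 with a 95% interval of -0.44 to 0.12.

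Of the 30 gene lists, 4 passed camera at the preset correlation, all lower in e_iTreg, and in none of them did a member pass over all genes. The type I interferon response list (29 measured members) had a mean difference of -0.10 and adjusted p = 0.00156. Trim30a, an interferon-induced regulator of that list, was at -0.38 ± 0.13. The oxidative phosphorylation list (51 members) was at -0.05 with adjusted p = 0.0108, and the cytosolic ribosomal protein list (57 members) at -0.03 with adjusted p = 0.0298. The resting or naive T cell list (13 members) was at -0.10 with adjusted p = 0.0298. Adjusted over the list alone, 1 of its members passed, lower, and its member with the smallest p, Igfbp4, was at -0.36 ± 0.10. With an estimated correlation the adjusted p was 0.960 for each of the 4 lists. Leaving out 1 array at a time kept the interferon call each time and ended that of the resting list (adjusted p up to 0.418), the oxidative phosphorylation list (up to 0.199) and the ribosomal list (up to 0.250). After quantile normalization 0 of the 30 lists passed, and above the median expression 2 others passed, both higher. None of the 4 lists passed in the other direction in any setting, but other lists newly passed as higher, 4 without eTreg replicate 1, 1 without eTreg replicate 2, 4 without e_iTreg replicate 3, 3 without e_iTreg replicate 4 and 5 with Xist and Y-linked genes as covariates.

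The second comparison, iTreg minus eTreg, set Treg sorted after depletion and IVIg, which the series calls induced, against endogenous Treg under HSA. In iTreg 1261 probe sets (1226 genes) rose and 1088 (1075 genes) fell, together 2349 of 23521, and 5103 had an unadjusted p under 0.05. Changes over 2-fold were seen in 297 that rose and 58 that fell. Gzmb, a serine protease of cytotoxic granules, rose most among named genes, by 4.18 ± 0.53 (18.1-fold), from 7.95 ± 1.26 in eTreg and 8.08 ± 0.99 in e_iTreg to 12.13 ± 0.43 in iTreg. The cell cycle phosphatase Cdkn3 rose by 2.90 ± 0.44 and Ifitm2, an interferon-induced membrane protein, by 2.86 ± 0.27 (adjusted p = 0.000153). The largest named falls were in Zbtb10, a zinc finger gene (-1.56 ± 0.29), Lrig1, a negative regulator of growth factor receptors (-1.46 ± 0.27), the ubiquitin ligase Neurl3 (-1.37 ± 0.17) and the sialyltransferase St8sia6 (-1.27 ± 0.21).

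**Figure D1:**
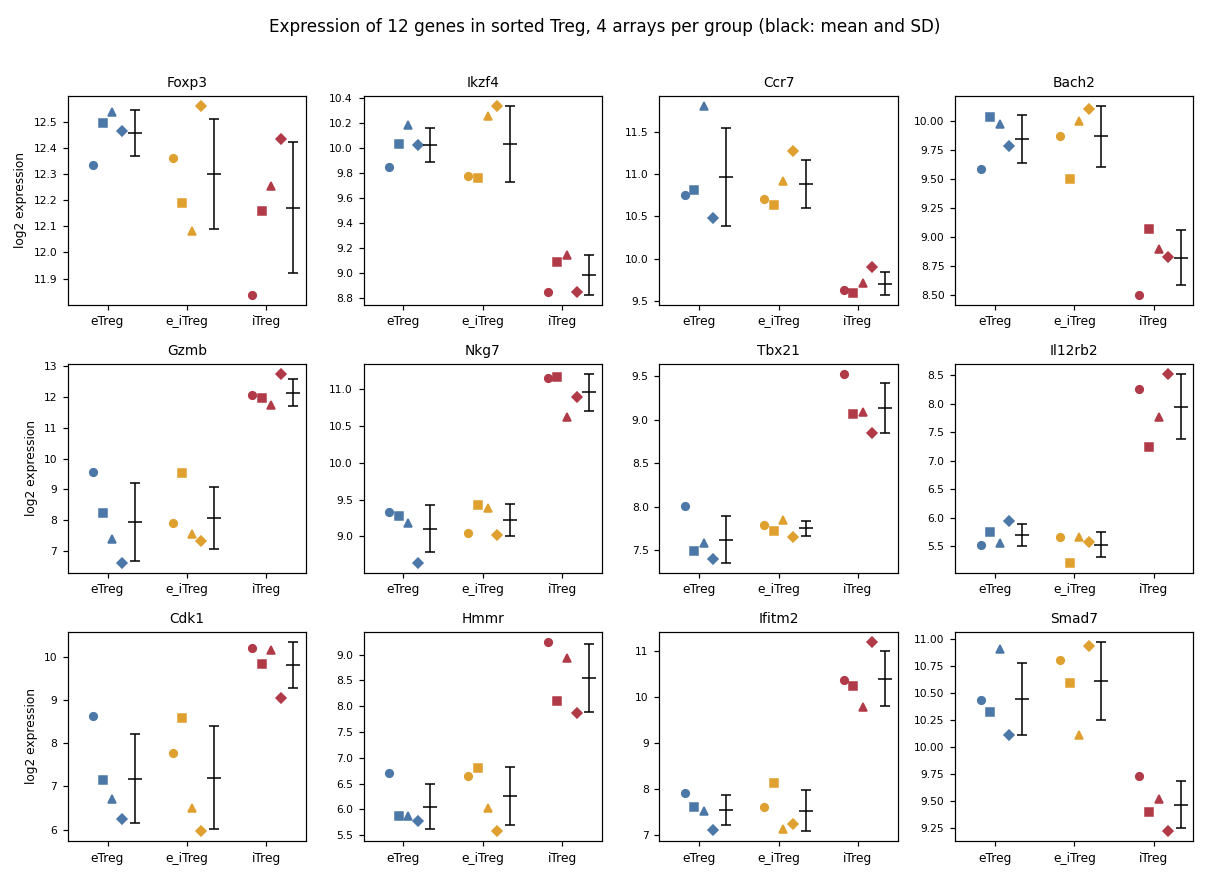
Log2 expression of 12 genes in each array (vertical axes, each panel with its own range) by group (horizontal axes), with marker shape for the replicate number and black bars for mean and SD of the 4 arrays. Gzmb lies at 12.13 ± 0.43 in iTreg against 7.95 ± 1.26 in eTreg, Ikzf4 is lower in iTreg by a log2 difference of -1.04, and Foxp3 differs by -0.29 between these groups without passing the test.

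Genes of type 1 helper (Th1) and effector Treg cells were among those that rose in iTreg. Of 13 measured Th1 genes, 8 rose and none fell over all genes tested, with 9 higher adjusted over the list alone (camera adjusted p = 4.7e-09; adjusted p = 0.0974 with an estimated correlation). Il12rb2, a chain of the IL-12 receptor, rose by 2.25 ± 0.22, the granule protein Nkg7 by 1.85 ± 0.17, the chemokine receptor Cxcr3 by 1.61 ± 0.21 and Tbx21, which encodes T-bet, the transcription factor of Th1 cells, by 1.51 ± 0.15. Of 24 effector Treg genes, 12 rose and none fell, with 15 higher adjusted over the list alone (adjusted p = 2.49e-10; adjusted p = 0.253 with an estimated correlation). They included the galectin Lgals1 (1.85 ± 0.34), the transcriptional repressor Prdm1 (1.04 ± 0.19) and the costimulator Icos (1.03 ± 0.21). Of 17 suppressive molecules, 6 rose and 2 fell, with 8 higher and 2 lower adjusted over the list alone (adjusted p = 0.00249; adjusted p = 0.296 with an estimated correlation). Gzmb, Gzma (2.20 ± 0.33) and the inhibitory receptor Havcr2 (1.79 ± 0.34) rose, and the fall was in Lrrc32, the surface anchor of latent TGF-beta (-0.80 ± 0.18), and Nt5e, the ectonucleotidase CD73 (-0.54 ± 0.12).

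The CD8 T and NK cell marker list passed camera, higher (16 members, adjusted p = 0.000386; adjusted p = 0.296 with an estimated correlation), with only 4 members past the threshold, all higher, both over all genes and adjusted over the list alone. These were Gzmb, Gzma, Nkg7 and Gzmk, a further granzyme (0.58 ± 0.10). Cd8b1, a chain of CD8, was at 0.15 ± 0.20, the chemokine Ccl5 at 0.05 ± 0.30 and the pore-forming Prf1 at -0.09 ± 0.11, none past the threshold. The median change of the 16 members was 0.24.

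Cell cycle genes rose almost throughout. Of 39 measured members, 38 rose over all genes and 39 adjusted over the list alone, with a mean change of 1.78 (adjusted p = 5.72e-37; adjusted p = 0.161 with an estimated correlation). The mitotic kinase Cdk1 rose by 2.63 ± 0.54, the chromosomal passenger Birc5 by 2.84 ± 0.52, the cyclins Ccna2 and Ccnb2 by 2.60 ± 0.57 and 2.56 ± 0.46, and Mcm3, of the replicative helicase, by 1.33 ± 0.19. The list mean varied widely within the other groups, from 7.06 to 8.46 in eTreg and from 7.09 to 8.53 in e_iTreg, and was 8.87 to 9.75 in iTreg. B cell markers varied too, between 6.69 and 8.55 in eTreg. Without the 3 arrays lowest in B cell markers (eTreg replicates 3 and 4 and e_iTreg replicate 4), which left 2 eTreg arrays, 8 of the 39 cell cycle genes passed, all higher, with a mean change of 1.39.

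**Figure D2:**
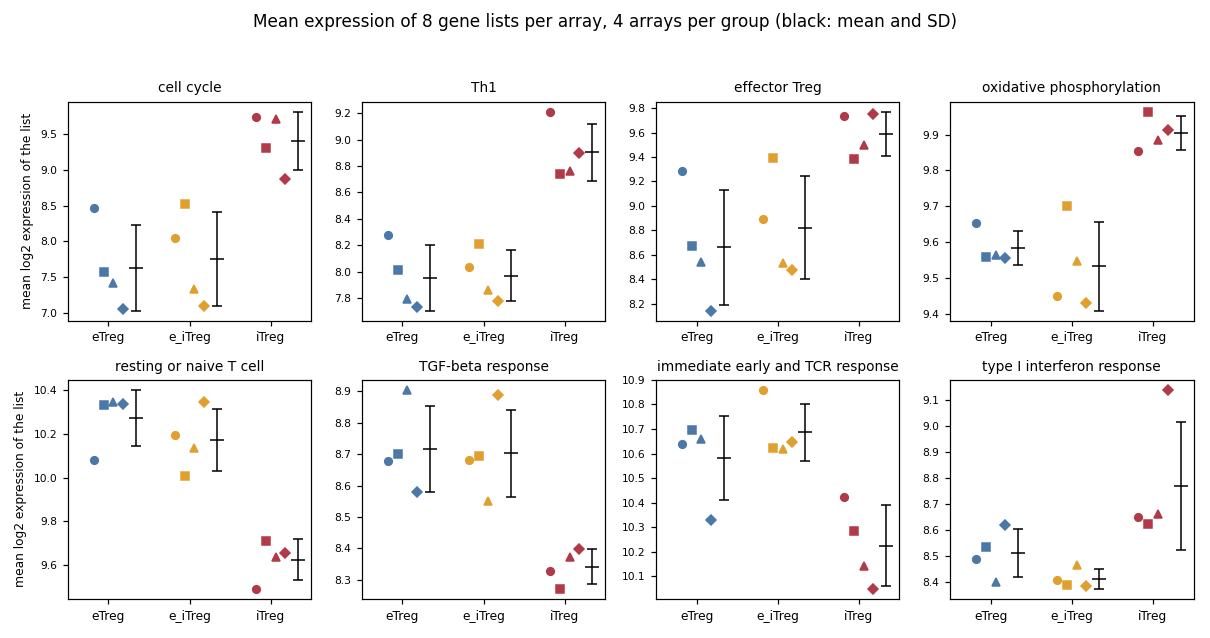
Mean log2 expression of 8 gene lists in each array (vertical axes, each panel with its own range) by group (horizontal axes), with marker shape for the replicate number and black bars for mean and SD of the 4 arrays. The cell cycle list runs from 8.87 to 9.75 in iTreg, above all arrays of eTreg (up to 8.46) and e_iTreg (up to 8.53).

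Genes of resting or naive T cells were among those that fell in iTreg. Of 13 members 9 fell and none rose, with 12 lower adjusted over the list alone (adjusted p = 3.84e-11; adjusted p = 0.0974 with an estimated correlation). The lymph node homing receptor Ccr7 fell by 1.26 ± 0.22, the transcription factors Bach2 and Foxp1 by 1.02 ± 0.15 and 0.91 ± 0.12, and the IL-7 receptor chain Il7r by 0.72 ± 0.13. Of 17 TGF-beta response genes 7 fell, with 11 lower adjusted over the list alone (adjusted p = 1.82e-05; adjusted p = 0.186 with an estimated correlation). Among these were Smad7 (-0.98 ± 0.19), Smurf1 (-0.78 ± 0.11) and Ldlrad4 (-0.82 ± 0.13), which are known as inhibitors of TGF-beta signalling. Of 26 immediate early and T cell receptor response genes 9 fell, with 15 lower and 1 higher adjusted over the list alone (adjusted p = 2.04e-06; adjusted p = 0.253 with an estimated correlation). Examples were the nuclear receptor Nr4a3 (-0.86 ± 0.21), Jun (-0.66 ± 0.15) and the NF-kB subunit Rel (-0.57 ± 0.14).

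Markers of Treg identity moved both ways. Of 20 Treg core genes 2 rose and 4 fell, with 3 and 7 adjusted over the list alone, and the list did not pass (adjusted p = 0.0642). Socs2, a target of STAT5, rose by 0.95 ± 0.19 and the actin-capping Capg by 0.56 ± 0.12. Ikzf4, the Treg transcription factor Eos, fell by 1.04 ± 0.14, as did Lrrc32, Nt5e and the folate receptor family member Izumo1r (-0.46 ± 0.11). Il2ra differed by -0.12 ± 0.14, Ctla4 by -0.10 ± 0.12, Ikzf2 by -0.04 ± 0.10 and Nrp1 by -0.32 ± 0.12, none past the threshold. The 5 thymus-derived Treg markers were lower as a list (adjusted p = 0.00106; adjusted p = 0.0974 with an estimated correlation), with Ikzf4 and Swap70 (-0.36 ± 0.10) past the threshold over all genes and 4 adjusted over the list alone.

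Metabolic and secretory lists passed as well, with part of their members past the threshold. Of 51 oxidative phosphorylation genes 24 rose and none fell, with 33 higher and 1 lower adjusted over the list alone (adjusted p = 2.44e-16; adjusted p = 0.161 with an estimated correlation), among them Cox5a of complex IV (0.92 ± 0.12) and Sdhb of complex II (0.58 ± 0.10). Of 20 glycolysis and hypoxia genes 7 rose, with 8 higher and 2 lower adjusted over the list alone (adjusted p = 0.00367; adjusted p = 0.253 with an estimated correlation). The glycolytic enzymes Tpi1 and Pgk1 rose by 1.29 ± 0.17 and 0.91 ± 0.16, and 1 member, the pyruvate dehydrogenase kinase Pdk1, fell by 0.49 ± 0.11. Of 22 unfolded protein response genes 8 rose, with 9 higher and 3 lower adjusted over the list alone (adjusted p = 0.000241; adjusted p = 0.232 with an estimated correlation). They included the endoplasmic reticulum proteins Sdf2l1 (1.59 ± 0.21) and Pdia6 (0.75 ± 0.12), and the chaperone Dnajb9 fell by 0.52 ± 0.11. Over the iTreg arrays this list (9.68, 9.45, 9.53 and 9.80 in replicates 1 to 4) had the same order as the plasma cell markers (8.06, 7.72, 7.84 and 9.46), with which it shares Xbp1 and Edem1. With the marker mean of other cells as a covariate 4 of the 22 rose and 1 fell, with a mean change of 0.20 against 0.29 without it.

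Of 27 homing receptors 9 rose and 2 fell, with 10 and 3 adjusted over the list alone (adjusted p = 0.000478; adjusted p = 0.296 with an estimated correlation). Ccr4 rose by 1.66 ± 0.28, Cxcr6 by 1.51 ± 0.23, Gpr15 by 1.46 ± 0.23 and the fucosyltransferase Fut7 by 1.10 ± 0.18, while Ccr7 and Ccr6 (-0.78 ± 0.13) fell. Of 13 Th2 genes, Ccr4, Maf (1.05 ± 0.23), Il4 (1.04 ± 0.19) and Epas1 (0.90 ± 0.23) rose, with 6 higher and 1 lower adjusted over the list alone (adjusted p = 0.00205; adjusted p = 0.253 with an estimated correlation). Of 12 Th17 genes, Ahr (0.93 ± 0.19), Il1r1 (0.79 ± 0.19) and Batf (0.75 ± 0.17) rose and Ccr6 fell, the same counts as adjusted over the list alone (adjusted p = 0.0302; adjusted p = 0.3 with an estimated correlation). Il4 and Il1r1 were dim, at 5.39 and 5.49 in eTreg and 6.43 and 6.28 in iTreg, near the log2 6 filter. The Th17 call was lost without eTreg replicate 4, iTreg replicate 1 or iTreg replicate 3 (adjusted p = 0.0883, 0.115 and 0.0706).

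Of 29 type I interferon response genes 4 rose, with 5 higher adjusted over the list alone (adjusted p = 0.000221; adjusted p = 0.34 with an estimated correlation). These were the nucleotide kinase Cmpk2 (1.20 ± 0.17), the antiviral Oas3 (1.11 ± 0.11), the membrane protein Bst2 (0.87 ± 0.19) and the ubiquitin-like Isg15 (0.82 ± 0.23). The list mean was 9.14 in iTreg replicate 4 against at most 8.66 in the other iTreg arrays, and without that array the list's adjusted p was 0.0596. Ribosomal protein genes were lower as a list (57 members, adjusted p = 0.00687; adjusted p = 0.468 with an estimated correlation), although its 1 member past the threshold, Rpl34, rose by 0.67 ± 0.19, with 0 adjusted over the list alone. Without iTreg replicate 4 the adjusted p of that list was 0.0992.

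Lists that did not pass were follicular helper genes (13 members, adjusted p = 0.502), Bcl2 family and apoptosis genes (20, adjusted p = 0.251), IL-2 and STAT5 response genes (13, adjusted p = 0.484), heat shock genes (10, adjusted p = 0.247), T cell identity genes (11, adjusted p = 0.129) and Fc receptors with IgG-binding lectins (20, adjusted p = 0.156). In the follicular helper list Sh2d1a (0.68 ± 0.12), Icos and Il4 rose and Bcl6, the transcription factor of those cells, fell by 0.81 ± 0.14, with 4 higher and 1 lower adjusted over the list alone. Its median change was -0.16 and its mean 0.12. In the apoptosis list the proapoptotic Bak1 rose by 0.77 ± 0.14, and the antiapoptotic Bcl2 (-0.86 ± 0.16) fell with the proapoptotic Bcl2l11 (-0.75 ± 0.13), Bbc3 (-0.59 ± 0.12) and Fas (-0.56 ± 0.17), with 3 higher and 6 lower adjusted over the list alone. In the IL-2 list Socs2 rose and Bcl2 and Cish (-0.53 ± 0.14) fell, the same counts as adjusted over the list alone. None of the heat shock, T cell identity or Fc receptor genes passed, over all genes or adjusted over the list alone.

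Markers of other cells were measured in the same sorted samples. B cell markers (19 members) had 0 past the threshold, over all genes or adjusted over the list alone, and a mean change of 0.37 (adjusted p = 0.0937), with list levels of 7.57 ± 1.01 in eTreg, 7.85 ± 0.81 in e_iTreg and 7.94 ± 0.21 in iTreg. That mean change ran from 0.0783 without eTreg replicate 3 to 0.700 without eTreg replicate 1. It was -0.496 without the 3 arrays lowest in B cell markers and -0.354 with the marker mean of other cells as a covariate. Neither of these negative values is evidence on B cells, since those arrays were chosen by this list and that marker mean holds its members. Plasma cell markers were higher as a list (10 members, adjusted p = 0.000221; adjusted p = 0.296 with an estimated correlation), with Prdm1 past the threshold over all genes and 6 adjusted over the list alone. Of the 10 members 4 are in other lists too, among them Prdm1 in the effector Treg list, as Bst2 below is in the interferon list. Jchain, the joining chain of secreted antibodies, was at 2.62 ± 0.81 (adjusted p = 0.0551) and at 1.53 without iTreg replicate 4, where it stood at 11.69 against 6.67 to 8.18 in the other 3. The list stood at 9.46 in iTreg replicate 4 against 7.72 to 8.06 in the other 3. Monocyte, macrophage and dendritic cell markers were higher as a list (23 members, adjusted p = 0.00764; adjusted p = 0.468 with an estimated correlation), with 3 past the threshold, Itgam (1.68 ± 0.29), Bst2 and the protease inhibitor Cst3 (0.57 ± 0.13), and 3 higher and 1 lower adjusted over the list alone. Without iTreg replicate 4 the adjusted p of that list was 0.335. Neutrophil markers were higher as a list (13 members, adjusted p = 0.000129; adjusted p = 0.33 with an estimated correlation), with 0 members past the threshold over all genes and 3 adjusted over the list alone, and the list stood at 7.60 in iTreg replicate 4 against at most 6.60 in the other 3. Erythroid (9 members, adjusted p = 0.266) and platelet markers (7, adjusted p = 0.882) had 0 members past the threshold, over all genes or adjusted over the list alone.

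In fits without 3 arrays, which leave fewer arrays in all, several lists had fewer members past the threshold. Fewer arrays alone lower such counts, so the counts do not show that a change shrank. Without the 3 arrays lowest in B cell markers 3 of 24 effector Treg genes rose (mean change 0.61 against 0.93 with all arrays), 4 of 13 Th1 genes, 2 of 17 suppressive molecules, 3 of 51 oxidative phosphorylation genes, 2 of 20 glycolysis genes and 1 of 22 unfolded protein response genes. In that fit 4 of 13 resting genes fell, as did 4 of 17 TGF-beta response genes and 3 of 26 immediate early genes. The 3 arrays with the signal of 1 sex were eTreg replicate 3, e_iTreg replicate 4 and iTreg replicate 4, the last of which also stood apart in interferon, plasma cell and neutrophil lists. Without them 7 effector Treg, 6 oxidative phosphorylation, 3 glycolysis and 4 unfolded protein response genes rose, and 3 TGF-beta response genes and 1 immediate early gene fell, while 39 of 39 cell cycle genes rose, 9 resting genes fell and 4 CD8 T and NK markers rose. The Th17 and myeloid lists no longer passed in the first of these fits, nor did the interferon, ribosomal, myeloid and neutrophil lists in the second. At the preset correlation 18 of the 20 lists still passed in the same direction in the first fit and 16 in the second.

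These calls came from limma's moderated test on 4 arrays per group. The count of 2349 fell to 1547 without eTreg replicate 2, 1487 without eTreg replicate 3, 1164 without the 3 arrays with the signal of 1 sex, 400 without the 3 arrays lowest in B cell markers and 1068 with the mean of B cell, plasma cell, myeloid and neutrophil markers as a covariate.

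The third comparison, iTreg minus e_iTreg, asked what differed with prior depletion when both groups had IVIg. In iTreg 1526 probe sets (1484 genes) rose and 1117 (1103 genes) fell, together 2643, with 6195 at an unadjusted p under 0.05. With each array centred on its median these were 2066 higher and 521 lower. Gzmb rose by 4.05 ± 0.53 (16.6-fold), Cdkn3 by 2.99 ± 0.44, Ifitm2 by 2.87 ± 0.27 and the related Ifitm3 by 2.58 ± 0.22. Falls included Zbtb10 (-1.72 ± 0.29), Lrig1 (-1.52 ± 0.27), Neurl3 (-1.32 ± 0.17), Apol9b (-1.30 ± 0.17), the Notch target Hey1 (-1.30 ± 0.23) and the costimulatory ligand Cd86 (-1.22 ± 0.15).

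Of 39 cell cycle genes 38 rose, 39 adjusted over the list alone, by a mean of 1.66 (adjusted p = 3.58e-34; adjusted p = 0.19 with an estimated correlation), with Cdk1 at 2.61 ± 0.54, Hmmr at 2.27 ± 0.32 and Mcm7 at 1.25 ± 0.17. Without the 3 arrays lowest in B cell markers 33 of the 39 passed, all higher. Of 13 Th1 genes 8 rose, 9 adjusted over the list alone (adjusted p = 1.65e-09; adjusted p = 0.162 with an estimated correlation), with Il12rb2 at 2.42 ± 0.22, Nkg7 at 1.74 ± 0.17 and Tbx21 at 1.38 ± 0.15. Of 24 effector Treg genes 10 rose, with 13 higher and 1 lower adjusted over the list alone (adjusted p = 7.79e-08; adjusted p = 0.303 with an estimated correlation). Of 17 suppressive molecules Gzmb, Gzma (1.99 ± 0.33), Havcr2 (2.10 ± 0.34), Lgals1 (1.79 ± 0.34) and the inhibitory receptor Lag3 (0.95 ± 0.17) rose, with 6 higher and 2 lower adjusted over the list alone (adjusted p = 0.00769; adjusted p = 0.341 with an estimated correlation). Nt5e (-0.61 ± 0.12) and Lrrc32 (-0.69 ± 0.18) fell, and without e_iTreg replicate 3 the list's adjusted p was 0.0607. In the CD8 T and NK list (16 members, adjusted p = 0.000542; adjusted p = 0.303 with an estimated correlation) 4 rose, Gzmb, Gzma, Nkg7 and Gzmk (0.52 ± 0.10), likewise 4 adjusted over the list alone.

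Of 13 resting or naive T cell genes 7 fell, 11 adjusted over the list alone (adjusted p = 9.92e-07; adjusted p = 0.19 with an estimated correlation), among them Ccr7 (-1.17 ± 0.22), Bach2 (-1.05 ± 0.15) and Foxp1 (-0.77 ± 0.12). Of 17 TGF-beta response genes 8 fell, 10 adjusted over the list alone (adjusted p = 0.000542; adjusted p = 0.243 with an estimated correlation), including Smad7 (-1.15 ± 0.19) and Ldlrad4 (-1.01 ± 0.13). Of 26 immediate early genes 13 fell, 17 adjusted over the list alone (adjusted p = 4.17e-07; adjusted p = 0.212 with an estimated correlation), including Nr4a3 (-0.99 ± 0.21) and Rel (-0.70 ± 0.14). Thymus-derived Treg markers were lower as a list (5 members, adjusted p = 0.0039; adjusted p = 0.175 with an estimated correlation), with Ikzf4 (-1.05 ± 0.14) and Swap70 (-0.42 ± 0.10) past the threshold and 4 adjusted over the list alone. In the Treg core list, which did not pass (20 members, adjusted p = 0.341), Socs2 (1.13 ± 0.19) and Capg (0.53 ± 0.12) rose and Ikzf4, Lrrc32, Nt5e and Izumo1r (-0.46 ± 0.11) fell, with 2 higher and 6 lower adjusted over the list alone. Foxp3 differed by -0.13 ± 0.13 and Nrp1 by -0.38 ± 0.12 (adjusted p = 0.0624).

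Of 51 oxidative phosphorylation genes 28 rose, with 36 higher and 2 lower adjusted over the list alone (adjusted p = 5.22e-21; adjusted p = 0.175 with an estimated correlation), with Cox5a at 0.88 ± 0.12. Of 20 glycolysis genes 6 rose, 6 adjusted over the list alone (adjusted p = 0.0011; adjusted p = 0.212 with an estimated correlation), with Tpi1 at 1.30 ± 0.17. Of 22 unfolded protein response genes 8 rose and Dnajb9 (-0.49 ± 0.11) and Atf4 (-0.34 ± 0.10) fell, with 10 higher and 3 lower adjusted over the list alone (adjusted p = 0.000207; adjusted p = 0.212 with an estimated correlation), and Sdf2l1 was at 1.55 ± 0.21. Of 29 interferon response genes 8 rose, with 15 higher and 1 lower adjusted over the list alone (adjusted p = 8.64e-09; adjusted p = 0.243 with an estimated correlation), among them Oas3 (1.14 ± 0.11), Rtp4 (0.79 ± 0.15) and Zbp1 (0.56 ± 0.13). Of 27 homing receptors 10 rose and Ccr7 and Ccr6 (-0.74 ± 0.13) fell, with 11 and 5 adjusted over the list alone (adjusted p = 0.000168; adjusted p = 0.285 with an estimated correlation). Of 13 Th2 genes Ccr4 (1.47 ± 0.28), Epas1 (0.86 ± 0.23), Il4 (0.80 ± 0.19) and Pparg (0.72 ± 0.21) rose, with 5 higher and 1 lower adjusted over the list alone (adjusted p = 0.00549; adjusted p = 0.285 with an estimated correlation).

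Among lists that did not pass, the Th17 list (12 members, adjusted p = 0.343) held rises in Ahr (0.80 ± 0.19), Batf (0.65 ± 0.17) and Il1r1 (0.62 ± 0.19) and the fall in Ccr6, with the same counts adjusted over the list alone. The follicular helper list (13, adjusted p = 0.703) held rises in Icos (0.80 ± 0.21), Il4, Sh2d1a (0.54 ± 0.12) and Slamf6 (0.42 ± 0.13) and falls in Bcl6 (-0.92 ± 0.14) and Tox (-0.45 ± 0.13), with 4 and 3 adjusted over the list alone, a median of -0.14 and a mean of 0.02. The apoptosis list (20, adjusted p = 0.341) held the rise in Bak1 (0.77 ± 0.14) and falls in Bcl2 (-0.71 ± 0.16), Bcl2l11 (-0.69 ± 0.13), Bbc3 (-0.57 ± 0.12), Fasl (-0.62 ± 0.15) and Tnfrsf10b (-0.74 ± 0.23), with 1 and 5 adjusted over the list alone. The IL-2 and STAT5 list (13, adjusted p = 0.678) held Socs2 and Bcl2, the heat shock list (10, adjusted p = 0.341) the fall in Bag3 (-0.37 ± 0.10), and the T cell identity list (11, adjusted p = 0.104) the rise in Thy1 (0.70 ± 0.16), with the same counts adjusted over each list alone. The ribosomal list (57, adjusted p = 0.421) held rises in Rpl34 (0.65 ± 0.19) and Rpl37 (0.48 ± 0.13), with 0 adjusted over the list alone. The probe set of Rpl37 was dim, at 5.73 in e_iTreg and 6.21 in iTreg, against list means of 10.08 and 10.02. Fc receptors (20, adjusted p = 0.308) had 0 members past the threshold either way.

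B cell markers (19 members, adjusted p = 0.341) had 0 past the threshold either way and a mean change of 0.09, which ran from -0.295 without e_iTreg replicate 4 to 0.311 without e_iTreg replicate 2. Plasma cell (10, adjusted p = 0.000801; adjusted p = 0.324 with an estimated correlation), neutrophil (13, adjusted p = 0.000542; adjusted p = 0.387 with an estimated correlation) and myeloid markers (23, adjusted p = 0.0103; adjusted p = 0.541 with an estimated correlation) were higher as lists. Without iTreg replicate 4 their adjusted p-values were 0.0692, 0.0875 and 0.430, and without e_iTreg replicate 4 that of the myeloid list was 0.0943. Past the threshold were Prdm1 (0.94 ± 0.19) among plasma cell markers, 0 neutrophil markers, and Itgam (1.71 ± 0.29), Bst2 (0.71 ± 0.19), Cst3 (0.47 ± 0.13) and, lower, Siglech (-0.45 ± 0.12) among myeloid ones, with the same counts adjusted over each list alone. Erythroid markers (9, adjusted p = 0.411) had Car2 (0.67 ± 0.18) past the threshold, also adjusted over the list alone, and platelet markers (7, adjusted p = 0.647) had 0, with 1 higher and 2 lower adjusted over the list alone. Car2 was dim, at 5.54 in e_iTreg and 6.21 in iTreg.

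Several lists again had fewer members past the threshold in fits without 3 arrays, while 5 of 17 suppressive molecules rose in both. Here too fewer arrays alone lower such counts, which do not show that a change shrank. Without the 3 arrays with the signal of 1 sex 4 of 24 effector Treg, 11 of 51 oxidative phosphorylation, 4 of 29 interferon response, 3 of 20 glycolysis and 3 of 22 unfolded protein response genes rose. In that fit 4 of 13 resting, 4 of 17 TGF-beta response and 5 of 26 immediate early genes fell, and the Th2, plasma cell, neutrophil and myeloid lists no longer passed. Without the 3 arrays lowest in B cell markers 14 oxidative phosphorylation, 5 interferon response, 3 glycolysis and 4 unfolded protein response genes rose, and 4 resting, 4 TGF-beta response and 8 immediate early genes fell, and the myeloid list no longer passed.

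The test was the same. The count of 2643 fell to 1747 without e_iTreg replicate 3, 1616 without e_iTreg replicate 4, 1730 without iTreg replicate 1, 1070 without the arrays with the signal of 1 sex, 1356 without those lowest in B cell markers, 1744 with the marker mean of other cells as a covariate and 1025 with Xist and Y-linked genes as covariates.

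Both iTreg contrasts shared the iTreg arrays, so their calls were not independent. Of the probe sets that rose, 1084 were shared, of those that fell 660, and 1 went in opposite directions. Independent lists of these sizes would share 81.8 and 51.7, which leaves out the shared arrays, and 50 simulations in which no group differed shared 0, so neither is a chance value for contrasts in which iTreg differs. Across genes, which are not independent replicates, the log2 changes of iTreg minus eTreg and iTreg minus e_iTreg correlated with r = 0.881. This lay just above the simulated range of -0.205 to 0.872 (mean 0.488). The covariance was 0.0908 against 0.0124 simulated (range -0.00344 to 0.0363). With the iTreg arrays split between the contrasts r was 0.663. The contrasts e_iTreg minus eTreg and iTreg minus eTreg, which share eTreg, correlated with r = 0.214, within the simulated range of -0.186 to 0.869. Their covariance was 0.0107 against 0.0115 simulated, and with eTreg split r was 0.0134. Without 1 array r ran from 0.0276 (e_iTreg replicate 2) to 0.406 (eTreg replicate 1).

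The position of the mixed population was then measured on a scale where 0 is the eTreg mean and 1 the iTreg mean, over the 2349 probe sets past the threshold between those groups. The e_iTreg arrays lay at 0.0720 ± 0.238 (SD, n = 4), from -0.184 to 0.372. Without 1 array their mean ran from -0.0322 (e_iTreg replicate 2) to 0.174 (eTreg replicate 1). The eTreg arrays themselves ranged from -0.172 to 0.316 and the iTreg arrays from 0.915 to 1.11, so the e_iTreg mean differed from eTreg by less than the spread between replicates. With the eTreg arrays split between the choice of genes and the origin of the scale the e_iTreg mean was -0.00994.

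**Figure D3:**
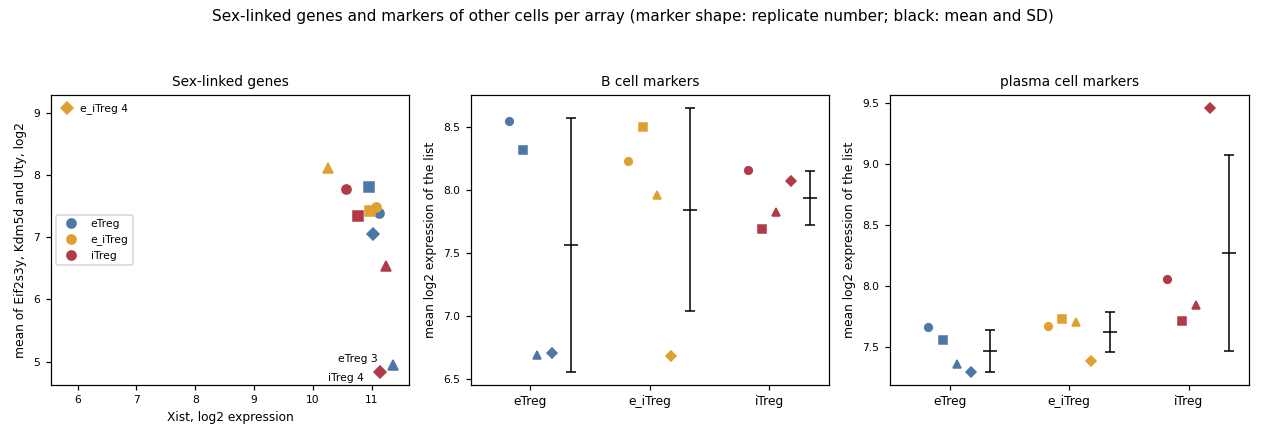
Left, Xist against the mean of the Y-linked genes Eif2s3y, Kdm5d and Uty in each array (both axes log2); middle and right, mean log2 expression of the B cell and plasma cell marker lists per array by group, with black bars for mean and SD of 4 arrays. Marker shape gives the replicate number. The plasma cell list is at 9.46 in iTreg replicate 4, and e_iTreg replicate 4 has Xist at 5.82.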

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

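Of the tests in this part, only that of the scaling of the arrays was written before its result was seen, and all others, including those of the splits, were chosen after. An array is named below where its gap to the nearest of the other 3 in its group was large against the range of the 4, which held for 22 of 429 groups of 4 values, and chance gives about 1 in 20.

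Granzyme, Th1 and cell cycle genes were higher in iTreg than in eTreg. The 16 CD8 T and NK markers had a median change of 0.24 (SD 1.15), against 2.02 for the 6 genes Gzmb, Gzma, Nkg7, Tbx21, Cxcr3 and Il12rb2. Of these 6, 3 (Gzmb, Gzma and Nkg7) are in both sets. The 6 genes were picked for their rise in these data, so their median was likely to lie above that of a fixed list. The comparison therefore does not decide on CD8 T or NK cells in the sort as a cause of the granzyme and Th1 part. It shows only that the list did not rise as a whole, with 4 of its 16 members past the threshold. Of the 16, 10 stood above log2 6 in the array lowest for that list, and a marker already bright rises less in log2 when RNA of other cells is added. Ccl5, Cd8b1 and Prf1, which did not pass, stood at 9.31, 8.88 and 7.90 in eTreg. With 1 pooled mean of B, plasma, myeloid and neutrophil markers as a covariate, 6 of these 6 genes stayed past the threshold (mean change 1.95 against 2.27 without it). Of 39 cell cycle genes 30 did (1.55 against 1.78), while fewer passed without the arrays lowest in B cell markers, as given above. This argued against cells that follow the pooled mean as the whole cause. Within eTreg and e_iTreg B cell markers varied most, so the fit cannot decide on plasma, myeloid or neutrophil cells taken singly. A share of the change from such cells stays open, and so does the part of the cell cycle genes that varied with B cell markers within eTreg and e_iTreg. An effect of the treatments on the cells stays open and was not tested, and IVIg and DTx cannot be separated in this contrast. Gzmb, Gzma, Nkg7, Tbx21, Cxcr3 and Il12rb2 stood at 8.08, 6.19, 9.22, 7.75, 9.02 and 5.53 in e_iTreg, given IVIg without DTx. In iTreg they stood at 12.13, 8.18, 10.96, 9.13, 10.48 and 7.95. No gene passed in e_iTreg minus eTreg, and 38 of 39 cell cycle genes rose in iTreg minus e_iTreg. By the series design this argues against IVIg without depletion as the whole cause over all sorted Treg. As e_iTreg is labelled a mixture, an effect on its induced Treg alone stays open.

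B cell markers differed widely between arrays of 1 group, with a range of the list mean of 1.86 in eTreg and 1.82 in e_iTreg against 0.463 in iTreg. After quantile normalization again the range in eTreg was 1.84. The deposited values had already been normalized between arrays, with eTreg array medians of 6.31 to 6.35. A second normalization could therefore change little within eTreg, and this test does not decide on scaling of the arrays. The array median of e_iTreg replicate 3 was 6.50, against at most 6.38 in all other arrays. B cells or their RNA in the sorted cells could account for it, since 18 of the 19 markers followed the mean of the others across arrays with r above 0.5 (median r 0.951, lowest 0.327 in Vpreb3). The group does not explain it, as it lies within groups, and no biological explanation was tested.

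Xist, expressed from the inactive X chromosome, and Y-linked genes were both high in most arrays. RNA of both sexes in 1 sample could account for it, since Xist and the mean of Eif2s3y, Kdm5d and Uty ran against each other over the 12 arrays (Spearman correlation -0.846, p = 0.00097). Y-linked probe sets that bind transcripts of the X-linked copies were argued against as the whole cause, since the mean of Kdm5d and Uty ranged over 3.74 and that of their X-linked copies Kdm5c and Kdm6a over 0.58. In e_iTreg replicate 4 Xist was at 5.82 (nearest 10.26) and the Y-linked mean at 9.09, in eTreg replicate 3 they were at 11.37 and 4.94, and in iTreg replicate 4 at 11.14 and 4.84. The sex of the animals was not given in the sources used here, and no biological explanation was tested.

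The 8 arrays of each contrast were regrouped into 35 splits of 4 and 4. For iTreg minus eTreg 1 of the 35, the real one, gave as many genes as 2349, with 0 in the highest other. For iTreg minus e_iTreg 1 of the 35, the real one, gave as many as 2643, with 1 in the highest other. A share of 1 in 35 is the smallest that these splits can give. The other splits set iTreg arrays on both sides, which adds the group difference to the spread within sides and lowers their counts. This argued against chance for both counts but could not exclude it. For e_iTreg minus eTreg the real split gave 0 genes, so that 35 of 35 gave as many, and the highest other gave 66. That split set replicates 1 and 2 of eTreg and e_iTreg against replicates 3 and 4, which points to a structure of the samples, although it was found as the highest of 34 other splits and was not tested further.

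Other arrays stood apart in single genes. In eTreg these were Bst2 in replicate 4 at 9.39 (nearest 10.11), Ctla4 in replicate 3 at 12.10 (11.72), Foxp1 in replicate 1 at 10.40 (10.71), Hmmr in replicate 1 at 6.70 (5.88), Ifi213 in replicate 4 at 7.97 (7.63) and Neurl3 in replicate 3 at 12.21 (11.85). In e_iTreg they were Car2 in replicate 3 at 5.17 (5.61) and Zfp820 in replicate 2 at 4.91 (4.63). In iTreg they were Cd46 in replicate 3 at 7.38 (6.73), Siglech in replicate 2 at 5.82 (6.04), Tpi1 in replicate 2 at 10.19 (10.60) and Zbp1 in replicate 4 at 11.04 (10.52).

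Other arrays stood apart in list means. In eTreg replicate 1 the thymus-derived Treg markers were at 9.82 (nearest 10.02), the resting or naive T cell list at 10.08 (10.33) and oxidative phosphorylation at 9.65 (9.56). Immediate early genes were at 10.33 in eTreg replicate 4 (10.64) and at 10.86 in e_iTreg replicate 1 (10.65). Fc receptors were at 6.33 in e_iTreg replicate 4 (6.70) and at 6.93 in iTreg replicate 4 (6.62), where the interferon list was at 9.14 (8.66) and neutrophil markers at 7.60 (6.60).

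Probe sets without a gene symbol, which the report's comparisons left out, also passed when fitted with all others. Of 16010 such probe sets 398 passed in iTreg minus eTreg (151 higher, 247 lower) and 550 in iTreg minus e_iTreg (198 higher, 352 lower), against 0 in e_iTreg minus eTreg. These were 2.49% and 3.44% of them, against 6.65% and 7.38% of named probe sets in the same fit.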

How the results depend on the processing

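Fits without arrays by sex signal or B cell markers, fits with marker or sex covariates, and the position with the eTreg arrays split, were chosen after the data were seen; all others were planned, and where a value moved the cause was not tested. In e_iTreg minus eTreg no gene passed in any setting, and the lists past the threshold went from 4 to 0 (estimated correlation, fry, quantile normalization), 2 (above the median expression, without the 1-sex arrays, without the low B cell arrays, with the B cell covariate, with the other-cell covariate) and 7 (Xist and Y-linked covariates), and ranged from 2 to 7 without 1 array. In iTreg minus eTreg the 2349 probe sets became 1089 at a fold of at least 1.5, 1164 without the 1-sex arrays, 400 without the low B cell arrays, 1068 with the other-cell covariate and 1487 to 2437 without 1 array, and the 20 lists 0 with the estimated correlation. In iTreg minus e_iTreg the 2643 became 1121, 1070, 1356 and 1744 in the same settings, 1025 with Xist and Y-linked covariates and 1616 to 2852 without 1 array, and the 18 lists 0 (estimated correlation) and 10 (fry). Of genes that had not passed, Ikzf2 in iTreg minus eTreg changed sign without the 1-sex arrays (0.0247; -0.0879 to 0.0237 without 1 array), and Ccl5 did so without the 1-sex arrays (-0.0253), without the low B cell arrays (-0.377), with the B cell (-0.168) and other-cell covariates (-0.296) and without 1 array (-0.112 to 0.296), as did Cd8b1 without the low B cell arrays (-0.131). The myeloid list in iTreg minus e_iTreg was at -0.0303 without the 1-sex arrays. Leaving out an array of the group outside a contrast cannot move that contrast's log2 changes, so their direction is then kept by construction. With 1 array left out, 972 values of named genes in iTreg minus eTreg and 793 in iTreg minus e_iTreg kept direction and side of the threshold, 29 and 105 no longer passed, 2 and 2 newly passed, and 5 and 0 changed sign. In the other settings 1156 and 978 kept both, 89 and 131 no longer passed, 3 and 4 newly passed, and 6 and 0 changed sign. Over all groups the replicate numbers did not clearly pair the arrays: 3 of 12 pairs had r above 0.1 (-0.151 to 0.247) and 4 of 12 arrays correlated best with their own number. Pairs of eTreg and e_iTreg were all positive, at 0.162, 0.0707, 0.0875 and 0.247 in replicates 1 to 4. Pairs with iTreg ran from -0.151 to 0.133, so a pairing of eTreg with e_iTreg stays open. With the replicate block 0, 2225 and 2394 probe sets and 4, 22 and 18 lists passed in the 3 contrasts in the order above. No background probes were used here, so the limit set by signal over background was not measured.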

Other observations

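The grouping of arrays and the genes in this paragraph were chosen after the result was seen. In the split of the 8 arrays without depletion that gave the most genes, replicates 1 and 2 of both groups differed from replicates 3 and 4 in 66 genes, of which 13 were B cell markers of the fixed list and 8 cell cycle genes. In replicates 3 and 4 against 1 and 2 the log2 difference was -2.26 in the complement receptor Cr2, -2.11 in the class II gene H2-Eb1, -1.62 and -1.58 in the B cell antigens Ms4a1 and Cd22, and -1.83 in the mitotic ubiquitin-conjugating enzyme Ube2c. Lgals1 and Ccr4, which were higher in iTreg than in both other groups, were at -1.11 and -0.94. The labels give no batch that goes with these numbers. In the same arrays Ighm stayed high, between 12.5 and 13.9 over all 12.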
